A study of Glycine max with 4 samples.

How the data were processed

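Degradome sequencing reads the 5' ends of uncapped RNA fragments, so that a cut made by a microRNA (miRNA) appears as a pile of read starts at 1 position of its target transcript. Degradome libraries were made from soybean (Glycine max cv. Williams 82), with 1 library in each of 4 groups of mixed tissues. RNA was isolated with TRIzol, and the libraries followed a published degradome protocol, per the labels' protocols. Each library was sequenced in a pair of runs, per the series' design text, and which run or runs each single-library table holds is not given in the sources used here. Reads were trimmed with cutadapt 1.4.2, per the submitters' processing notes. The tables carry the columns of the slice site caller CleaveLand4, and the aligner and genome build are not given in the sources used here.

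Each row of a deposited table pairs a query small RNA with a slice position on a transcript. The authors' tables give a p-value for each row, per the file headers, which is not adjusted for the number of rows. They give a degradome category, an ordered class, and an alignment penalty named Allen score, per the file headers. Category 0 stands for a slice position that is the single highest of its transcript, category 1 for a tied maximum, category 2 for a position above the transcript's average and category 3 for one at or below it. An Allen score of 0 is a match without penalty. The deposited minimum free energy ratio is a fraction, the energy of the duplex at the site relative to that of a perfect duplex. The tables also give the duplex free energies and the slice position on the transcript, per the file headers. The 4 single-library tables held 2120 rows (leaf), 1901 (rootstem), 2054 (flower) and 1840 (seed), and a table of all libraries combined held 2240. In all 5 tables the categories ran from 0 to 3, each p-value was under 0.05 and each free energy ratio was at least 0.65. Sites beyond those limits were not analysed here, so an unlisted pair is not shown to be uncut. Transcripts came from 2 releases, Phytozome 7 and Phytozome 8, named in the authors' tables. The files hold no read counts, so the depth of each library is unknown.

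Queries were grouped into families by their number: those with a miR number (430 of 2612 queries, in 150 families) and those with an m number in place of it (2182). Queries of the 5p and 3p arms were pooled within a family. The known targets of a family may therefore refer to only 1 of its arms. A pair is a family and a gene locus. It was called supported in a library where at least 1 row had a category of 2 or lower and a p-value of at most 0.05, and its category was the lowest of those rows. The 3068 locus IDs were looked up in the gene table of the assembly Glycine_max_v4.0, and 0 matched. The files do not pair the IDs with gene names, so targets are described by the miRNA family that matched them. The comparison of targets with the classes known for each family was therefore not run.

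With 1 library per group there was no test between groups and no difference has a replicate check. Shares carry exact (Clopper-Pearson) 95% binomial intervals, which cover counting error only and treat pairs as independent. Overlaps are given as the Jaccard index, the shared pairs divided by the pairs in either library. Families were placed in 6 lists fixed before the data were examined. The share of a list's pairs supported in a library was set beside 10000 random sets of the same size. The sets were matched on broad classes of the number of rows per pair. They were drawn from all supported pairs, the list's own included. The resulting percentile describes these libraries and is not a test. Agreement of categories was measured with Cohen's kappa over pairs with a row in both libraries.

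Items named in the text followed a rule fixed before the data were examined. It took pairs in category 0 in all 4 libraries ranked by mean log10 p, at most 1 per family and the first 10. It took, for each library, category 0 pairs with no row in the other 3 libraries, lowest p first, at most 1 per family and the first 5. It took for each listed family the pair with the lowest p, and ties went to the lower Allen score and then to the ID. Because IDs have no names here, most are given by family alone. Further families outside this rule were chosen after their values were seen and are marked so.

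Alternatives changed the category limit, the p limit, the Allen score limit, the unit counted, the tolerance on slice positions and the libraries included. Others, on the query length and naming, the transcript release, repeat sequence and the alignment rank, were added after seeing the data. The deposited p-values followed 1 minus (1 - f) to the power k, where f is a frequency particular to each table, release and category and k a whole number particular to the alignment. With a tolerance of 0.02 on k, 100% of the 10155 rows fitted in the 40 groups of rows. Each of the 2484 combinations of query and slice position listed in at least 2 tables had the same k in each table. This allowed the p-value of an alignment to be computed for a category or table in which it was not listed. The steps were tested on simulated data: f was recovered within 0.1% in 100% of 200 sets of p-values. Each set was built to hold a k of 1, or of 2 and 3, which made recovery close to certain. The smallest group of rows in the data held 13. Of 100 simulated lists without an effect, 3 lay above the 95th percentile. Their members were drawn independently, unlike the pairs of a family, and low percentiles were not checked. Scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.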

Results

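The data describe where transcripts were cut in 4 parts of the soybean plant, as read from degradome libraries. The leaf library mixed 4 tissues, cotyledons and new leaves of the germination and trefoil stages. The rootstem library mixed 2 tissues of germinating plants, root and stem. The flower library mixed 2 kinds of flower bud, from bud differentiation and from flowering. The seed library mixed 4 tissues, pods of 1, 2 and 3 weeks and developing seeds of about 6 weeks. Each group had 1 library, so no value below has a replicate error, and the depth of the libraries is unknown.

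The first comparison asked how many pairs of a query family and a cut locus each part of the plant held. Most came from m-numbered queries, which the labels do not describe and which are not shown here to be miRNAs. The leaf library had the most supported pairs, 1109, followed by flower with 1045, seed with 952 and rootstem with 947. Queries with a miR number gave 226 pairs in leaf, 205 in rootstem, 198 in flower and 177 in seed. The m-numbered queries gave 883, 742, 847 and 775 pairs in the same order. The supported pairs lay on 859 gene loci in leaf, 747 in rootstem, 799 in flower and 768 in seed. These counts were not scaled to depth, which the tables do not give.

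A larger share of the pairs of miR-numbered families lay at the strongest cut sites, although the m-numbered queries had more such pairs, 248 to 302 per library against 73 to 112. A category 0 site, the single highest position of its transcript, was the best evidence for 56.6% of their pairs in flower (95% interval 49.4 to 63.6), 50.2% in rootstem (43.2 to 57.3), 48.2% in leaf (41.6 to 55.0) and 41.2% in seed (33.9 to 48.9). Among the m-numbered queries the share was 34.2% in leaf (31.1 to 37.4), 33.4% in rootstem (30.0 to 36.9), 32.1% in flower (29.0 to 35.4) and 32.4% in seed (29.1 to 35.8). Over all queries it was 37.1% in leaf, 37.1% in rootstem, 36.7% in flower and 34.0% in seed, with intervals that overlapped. In seed the intervals of the miR-numbered and m-numbered queries overlapped too. A pair's category was the lowest of its rows, so a pair with more rows had more chances of category 0. In leaf the 96 pairs of the transcription factor list described below had 599 combinations of query and transcript. All 1109 leaf pairs together had 1730. The shares were not matched on the number of rows per pair. The intervals of the miR-numbered families in flower and seed did not overlap, at 112 of 198 and 73 of 177 pairs. An interval over pairs of 1 library does not cover the variation between plants. It also treats pairs as independent, although several can share a site: the leaf pairs lay at 904 slice positions. The intervals can therefore be too narrow.

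**Figure D1:**
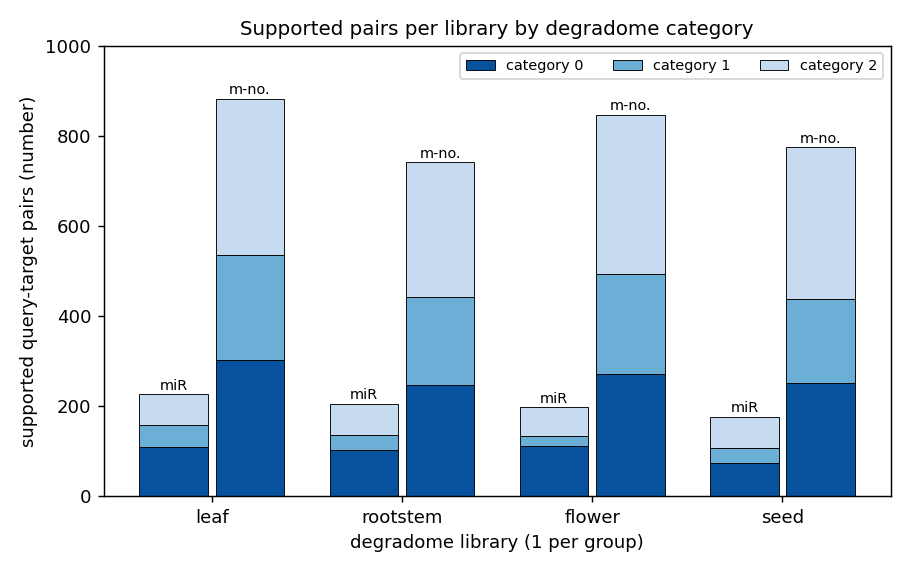
Number of supported pairs of query family and target locus (vertical axis) in each of the 4 libraries (horizontal axis), with 1 bar for miR-numbered queries (miR) and 1 for m-numbered queries (m-no., not described in the labels), divided by the best degradome category of the pair. The m-numbered bars range from 742 to 883 pairs and the miR-numbered bars from 177 to 226.

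Transcription factor families made up the largest of the fixed lists and were least represented in seed. The list holds families known to cut transcripts of developmental regulators, such as miR156 (SPL factors), miR172 (AP2 factors), miR319 (TCP factors) and miR396 (growth-regulating factors). Of its 159 pairs, 96 were supported in leaf (60.4%, 52.3 to 68.0), 91 in rootstem (57.2%, 49.2 to 65.0), 95 in flower (59.7%, 51.7 to 67.4) and 64 in seed (40.3%, 32.6 to 48.3). The seed share stood at percentile 1.83 of the random sets of pairs, against 86.7 in leaf, 95.7 in rootstem and 54.3 in flower. Category 0 sites numbered 35 in seed, 60 in leaf, 57 in rootstem and 72 in flower. Across the list 39 pairs were supported in all 4 libraries and 70 in 1 library only. The difference has no replicate check. Restricted to the 70 list pairs whose alignments could have been listed at categories 0 to 2 in each library, a choice made after seeing the data, the counts were 48, 46, 52 and 39 in leaf, rootstem, flower and seed.

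Single families of this list differed in where they were seen. The miR156 family had 29 supported pairs in leaf, 27 in rootstem, 27 in flower and 19 in seed, and 15 of its 43 pairs were supported in all 4 libraries. Its pair with the lowest p, on the transcript Glyma19g26390.1, was cut at position 1472 in all 4 libraries in the site GUGCUCUCUAUCUUCUGUCAA, with an Allen score of 0. The miR396 family had 16 pairs in flower, 13 of them in category 0, against 9 in leaf, 5 in rootstem and 2 in seed. Neither of the 2 seed pairs was in category 0 or 1. The miR319 family had all 12 of its pairs in rootstem, 11 of them in category 0, with 9 in flower, 7 in leaf and 3 in seed. The miR169 family had 16, 13, 16 and 14 pairs in leaf, rootstem, flower and seed, and miR172 had 12, 11, 12 and 9. The miR171 family had 11, 9, 7 and 7 pairs in that order and miR164 had 4, 7, 6 and 6. The miR159 family had 5, 4, 2 and 4 pairs. The miR166 family had 3 pairs each in leaf and rootstem and 0 in flower and seed, but none in any library with an Allen score of at most 4. All 20 miR396 pairs could have been listed in each library at category 0 or 1, but only 3 of them at category 2, and for miR319 the numbers were 12 and 2. Over alignments that could be listed at categories 0 to 2 in each library, miR396 had 1 pair in each library. The miR319 family had 1, 2, 1 and 0 such pairs in leaf, rootstem, flower and seed. Both families left too few pairs there to show or exclude a contrast. With Allen scores of at most 4, miR396 had 7, 4, 15 and 0 pairs and miR319 had 6, 11, 8 and 3 in that order, and at a p limit of 0.01 they had 6, 3, 14 and 0 and 7, 11, 9 and 3. The miR166 family had 0 pairs in each library over alignments that could be listed in each.

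Auxin families ran the other way, with the most pairs in seed. Of the 44 pairs of miR160, miR167, miR390 and miR393, families known to act on auxin signalling, 28 were supported in seed (63.6%, 47.8 to 77.6), 22 in leaf (50%, 34.6 to 65.4), 21 in rootstem (47.7%, 32.5 to 63.3) and 20 in flower (45.5%, 30.4 to 61.2). The seed share stood at percentile 99.6 of the random sets, with 19.2 in leaf, 21.9 in rootstem and 3.65 in flower. The intervals of all 4 libraries overlapped. The list pools 5p and 3p queries, and its miR167 pair with the lowest p was of gma-miR167g-3p. At the main limits the excess lay in miR393, a family known to cut auxin receptor transcripts, with 16 pairs in seed and 9 in each other library. A core of 8 miR393 pairs was supported in all 4 libraries, with a median Allen score of 1.5, while the 8 pairs supported in seed alone had a median Allen score of 8 and none under 6. Of the 8 pairs supported in seed alone 7 were in category 0. With categories 0 and 1 only, miR393 had 5 pairs in leaf, 3 in rootstem, 7 in flower and 13 in seed. With Allen scores limited to 4, miR393 had 8 pairs in each library. The whole auxin list then had 15 in leaf, 16 in rootstem, 16 in flower and 19 in seed, so seed still had the most. At a p limit of 0.01 the auxin list had 12 pairs in seed, 13 in leaf, 11 in rootstem and 14 in flower, so seed no longer had the most. Over alignments that could be listed at categories 0 to 2 in each library, the list had 16 in seed, 15 in flower, 12 in leaf and 11 in rootstem. The miR393 family had 7 of them in each library.

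The remaining lists were small. Families of the small RNA pathway list, known to act on Dicer and Argonaute transcripts, had 7 of 12 pairs supported in seed, 6 in flower, 4 in rootstem and 2 in leaf. Within it miR168 had 4 pairs in seed, 1 in rootstem, 1 in flower and 0 in leaf. In category 0 or 1 it had 1 pair in seed, 1 in flower and 0 in leaf and rootstem. With Allen scores of at most 4 it had 2 in seed and 0 in each other library. Disease resistance families had 7 of 14 pairs in rootstem, 6 in leaf, 3 in flower and 1 in seed, and 5 of the rootstem pairs came from miR2109, all in category 0. Rootstem did not have the most at a p limit of 0.01, with 1 pair against 2 in leaf, 0 in flower and 0 in seed. Over alignments that could be listed in each library it had 0, against 1 in leaf, 2 in flower and 0 in seed. With categories 0 to 3 leaf had 10 pairs and rootstem 7. The nutrient and copper list had 13 of 23 pairs in rootstem, 11 in leaf, 11 in flower and 7 in seed, and miR408 accounted for 6, 5, 5 and 4 of them. The list of other conserved or legume families had 9 of 15 pairs in leaf, 4 in rootstem, 5 in flower and 9 in seed. Intervals at these sizes were wide: the seed share of the disease resistance list, 7.14%, ran from 0.181 to 33.9%, and the rootstem share, 50%, from 23.0 to 77.0%.

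**Figure D2:**
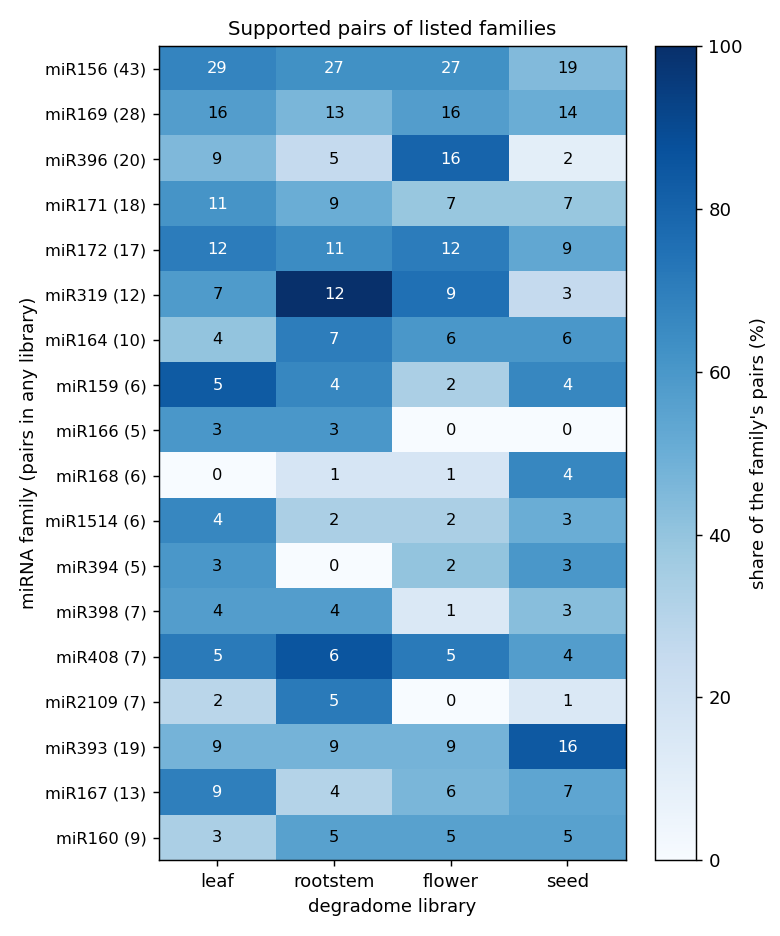
Number of supported pairs (printed in each cell) of the listed miRNA families with at least 5 pairs (rows, with the pairs seen in any library in brackets) in the 4 libraries (columns), shaded by the share of the family's pairs in percent. The miR396 family has 16 pairs in flower and 2 in seed, miR319 has 12 in rootstem and 3 in seed, and miR393 has 16 in seed and 9 in each other library. Over alignments that could be listed at categories 0 to 2 in each library, miR396 has 1 pair in each, miR319 has 1, 2, 1 and 0 (leaf, rootstem, flower, seed) and miR393 has 7 in each.

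The next comparison asked how many cuts were common to the plant. Most pairs were supported in 1 library only: 2521 of the 3090 pairs in any library (81.6%, 80.2 to 82.9). The share was 64.0% for miR-numbered families and 58.0% with Allen scores of at most 4. The p-values are not adjusted for the number of rows, and how many single-library pairs are chance calls was not tested. A further 304 were supported in 2 libraries, 136 in 3 and 129 in all 4. Pairs of miR-numbered families recurred more, with 60 of 475 in all 4 libraries (12.6%, 9.78 to 16.0), than those of m-numbered queries, with 69 of 2615 (2.64%, 2.06 to 3.33). That comparison too was not matched on the number of rows per pair. Leaf and flower shared the most, 319 pairs (Jaccard index 0.174), and rootstem and seed the fewest, 182 (0.106). The index was 0.156 for leaf and rootstem, 0.149 for rootstem and flower, 0.132 for flower and seed and 0.118 for leaf and seed. Over miR-numbered families alone the highest value was that of leaf and rootstem, 0.339, followed by rootstem and flower, 0.330, and leaf and flower, 0.321. The 3 values with seed were then 0.248 (leaf), 0.248 (rootstem) and 0.284 (flower).

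The pairs cut at their transcript's highest position in every library were in the majority pairs of miR-numbered families. There were 45 pairs in category 0 in all 4 libraries, 25 of them of miR-numbered and 22 of listed families. The first 10 by the authors' deposited p were pairs of miR156, miR171, m7042, miR169, miR1509, miR403, miR164, m0200, m3372 and miR172. The m7042 query matched the miR156 site at position 1472 named above, and the m0200 pair had the same locus and slice position as the miR164 pair. The site of the m3372 pair contained the full reverse complement of the miR159 query gma-miR159b-3p, so this pair may not be separate from a miR159 site. Position 1768 of Glyma01g18040.1, in the miR171 site UGGGAUAUUGGCGCGGCUCAA, had deposited p-values from 0.000295 in rootstem to 0.000343 in seed. The miR403 pair, of a family known to act on Argonaute transcripts, had an Allen score of 3 and a deposited p from 0.00118 in rootstem to 0.00137 in seed.

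Each library also had strong sites with no listing of any category elsewhere. There were 218 such category 0 pairs in leaf, 193 in rootstem, 175 in flower and 216 in seed, of which 28, 28, 28 and 25 were of miR-numbered families. Several queries can match 1 site, and these pairs lay at 168, 162, 148 and 190 slice positions. In leaf the first 5 were pairs of m0976, m6960, m6872, m6438 and miR4343, and in rootstem of m4510, miR4408, m0704, m0902 and m4986. In flower they were pairs of m0390, m0405, m1795, miR156 and m6959. Each of these sets of 5 held 4 slice positions, since m0976 and m6960, m4510 and m4986, and m0390 and m1795 shared theirs. In seed they were pairs of m2539, miR167, m6436, miR156 and m4142. The flower pair of miR156 lay in the site AUGCUCCCUCUCUUCUGUCAA (Allen score 3, authors' deposited p 0.000313). The seed pair of miR167 lay in the site GGUGCAUGCAGCCACGUGAUCA (Allen score 4, deposited p 0.000685). A pair absent from a table had no site within the table's limits, which does not show that it was uncut.

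Pairs with better matches were more often listed in several libraries. Among miR-numbered families, 78.5% of the 107 pairs with an Allen score of 0 to 2 were supported in 2 or more libraries (69.5 to 85.9), as were 50% of the 80 pairs from 2.5 to 4 (38.6 to 61.4). The share was 15.1% from 4.5 to 6 (8.30 to 24.5), 17.2% from 6.5 to 8 (10.2 to 26.4) and 16.5% above 8 (10.1 to 24.8). Among m-numbered queries it was 33.3% of 102 pairs at 0 to 2 (24.3 to 43.4) and 27.6% of 239 from 2.5 to 4 (22.05 to 33.75). In their further classes it was 16.2%, 14.3% and 10.5%. The division by Allen score, the best over the libraries, was chosen after seeing the data, and a better match ranks higher among a query's alignments and can be listed at more categories. Over alignments that could be listed at categories 0 to 2 in each library, the share for miR-numbered families was 66.7% at scores up to 4 (57.5 to 75.01) and 26.7% above (18.4 to 36.5). For m-numbered queries it was 28.4% (22.55 to 34.9) and 22.8% (19.9 to 25.9), with intervals that overlapped.

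**Figure D3:**
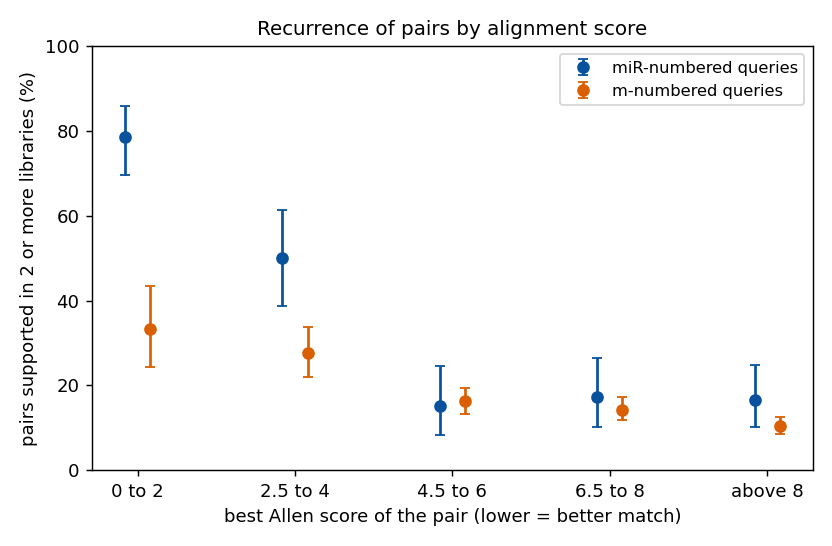
Share of pairs supported in 2 or more of the 4 libraries (vertical axis, percent) by the best Allen score of the pair (horizontal axis, lower is a better match), for miR-numbered and m-numbered queries. Points are shares and bars exact 95% binomial intervals. Shares fall from 78.5% to 16.5% for miR-numbered queries and from 33.3% to 10.5% for m-numbered queries between the first and last class.

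Where a pair was listed in a pair of libraries, its category was the same in most cases. The share with the same category was highest for leaf and rootstem, 73.8% of 378 pairs (kappa 0.618), and lowest for flower and seed, 56.7% of 363 (kappa 0.380). The 3 comparisons with seed had the lowest kappa values, 0.460 with leaf, 0.480 with rootstem and 0.380 with flower. Leaf and flower had 0.516 and rootstem and flower 0.529. Part of this agreement may be set by the p limit, since an alignment had the same k in each table. In leaf, Phytozome 8 alignments could be listed at category 0 up to a k of 172, but at category 2 only up to 11. An alignment with a high k could thus be listed only at the stronger categories, which kappa does not take into account.

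Category 0 sites of miR-numbered families had a lower median Allen score than their sites of each other category. Over all pairs the median Allen score of category 0 was 6.5 in leaf, 6.5 in rootstem, 6.25 in flower and 6.75 in seed, and that of category 2 was 6 in each library. The order turned when each row was counted, with a median of 4 in each library for category 0 and of 5 in leaf and 4.5 in the other libraries for category 2. For miR-numbered families the median of category 0 was 3 in each library, and that of category 1 lay between 4.75 (flower) and 6.75 (rootstem). Their median of category 2 was 5 in leaf, 3.5 in rootstem and 4 in flower and seed. That of category 3 was 7.5 in leaf, rootstem and seed and 6.25 in flower. For m-numbered queries the median of category 0 was 7.5 in leaf, rootstem and flower and 7 in seed. That of category 1 was higher, 8 in leaf, rootstem and flower and 7.5 in seed. That of category 2 was lower, 6.5 in leaf, rootstem and seed and 6.25 in flower. That of category 3 was 6.5 in leaf, rootstem and seed and 7 in flower. The median free energy ratio of category 0 pairs lay between 0.723 (seed) and 0.734 (leaf). Category 2 and 3 sites had to rank higher among a query's alignments to reach the p limit, so these medians compare sites selected by different rules.

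The table of all libraries combined was set beside the single libraries. It held 1142 supported pairs, 238 of them of miR-numbered families. Of these 164 were supported in 0 of the single libraries, 627 in 1, 162 in 2, 83 in 3 and 106 in all 4. In the other direction, 23 of the 129 pairs supported in all 4 libraries, 53 of the 136 in 3 and 142 of the 304 in 2 were not supported in the combined table. The category 0 share of miR-numbered pairs was 57.1% in the combined table (50.6 to 63.5), against 29.8% for m-numbered queries (26.8 to 32.9). These shares were again not matched on the number of rows per pair. The combined table is described as all libraries combined, so it is not an independent measurement. Whether it holds exactly the reads behind the single-library tables is not given in the sources used here.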

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

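Values that follow one another are in the order leaf, rootstem, flower and seed, and the alternatives on alignment rank, query length, query naming, transcript release, repeats, gene locus and miR-numbered queries were chosen after seeing the data. Of 848 recomputed values 602 stayed within a factor of 1.5 (counts), their 95% interval (shares and Jaccard indices), the range over library pairs (kappa) or 0.5 (median Allen scores), and 246 moved beyond it. Of the 848, 133 came from settings that add nothing (no p limit, p at most 0.05) or repeat another (categories 0 to 4); without them 480 of 715 stayed, and 221 of those equalled the reported value. Seed had the fewest transcription factor list pairs in each of the 10 settings that changed the list's counts. Of the 13 that changed the Jaccard indices, leaf and flower had the highest in 10, and leaf and rootstem in the other 3 (Allen score limit, query and transcript, miR-numbered queries). Rootstem and seed had the lowest in 11 of the 13, and leaf and seed in the others (query and transcript, miR-numbered queries). Lifting the p limit and allowing category 4 added nothing, since the tables hold only p-values under 0.05 and categories up to 3. The comparison with known target classes was not run under any setting. Depth limits all counts and is unknown. Where the unit or the sites counted did not change by construction, the cause was not tested.

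With categories 0 and 1 only, supported pairs numbered 693, 577, 627 and 544, and the category 0 share was 59.3, 60.8, 61.2 and 59.6%. Pairs in all 4 libraries numbered 56 and the share in 1 library only was 85.9%. The Jaccard index was 0.138 (leaf and flower) and 0.0686 (rootstem and seed), and auxin list pairs numbered 14, 11, 14 and 20. The combined table had 109 pairs supported in no single library and lacked 57 of those in at least 2.

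With categories 0 to 3, and equally 0 to 4, the category 0 share was 27.8, 26.9, 27.8 and 24.9%, the share in 1 library only 79.0%, the index of rootstem and seed 0.124, and 421 pairs of at least 2 libraries were not in the combined table.

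At a p limit of 0.01, supported pairs numbered 383, 302, 335 and 299, with a category 0 share of 53.3, 51.0, 51.3 and 43.5%. Pairs in all 4 libraries numbered 61, and 76.3% were in 1 library only. The index was 0.234 (leaf and flower) and 0.149 (rootstem and seed). Rootstem had 59 transcription factor list pairs, and the auxin list had 13, 11, 14 and 12. The combined table had 49 pairs of its own and lacked 82 of at least 2 libraries.

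With Allen scores of at most 4, supported pairs numbered 251, 209, 286 and 234, with a category 0 share of 51.0, 49.3, 47.6 and 39.7%. The share in 1 library only was 58.0%, and the index 0.366 (leaf and flower) and 0.311 (rootstem and seed). The combined table had 28 pairs of its own and lacked 42.

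Counted by slice position, 83.5% were in 1 library only and the index of leaf and flower was 0.151, or 0.155 with positions matched within 1 nt. Counted by query and transcript, there were 1730, 1500, 1688 and 1470 units, with a category 0 share of 47.6, 45.1, 49.3 and 38.4%. Of these 372 were in all 4 libraries and 74.2% in 1 only, and the index was 0.251 (leaf and flower) and 0.200 (rootstem and seed). The transcription factor list had 599, 542, 608 and 433 and the auxin list 106, 100, 111 and 152. The combined table had 290 of its own and lacked 374. Counted by gene locus, 78.8% were in 1 library only.

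Over alignments that could be listed at categories 0 to 2 in all 4 libraries, supported pairs numbered 486, 375, 522 and 455, with a category 0 share of 21.2, 20, 18.8 and 15.8%. The share in 1 library only was 71.5%, and the index 0.252 (leaf and flower) and 0.186 (rootstem and seed). The transcription factor list had 48, 46, 52 and 39 pairs, and the auxin list 12, 11, 15 and 16. The miR396 family had 1 pair in each library. The combined table had 77 pairs of its own and lacked 141.

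Over miR-numbered queries, supported pairs numbered 226, 205, 198 and 177, with a category 0 share of 48.2, 50.2, 56.6 and 41.2%. Pairs in all 4 libraries numbered 60 and 64.0% were in 1 library only, with an index of 0.321 (leaf and flower) and 0.248 (rootstem and seed). The combined table had 19 pairs of its own and lacked 41. Queries of 20 to 22 nt gave a category 0 share of 40.2% in leaf, and Phytozome 8 transcripts alone gave 41.5, 41.1, 40.7 and 37.5%.

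Leaving out each library in turn, the share in 1 of the remaining 3 libraries ran from 80.4% (without seed) to 85.1% (without flower), with 84.3% without leaf, and the pairs in all 3 numbered 147 (without leaf) to 188 (without seed). Taken over rows in place of pairs, the median Allen score of category 0 was 4 in each library and that of category 2 was 5, 4.5, 4.5 and 4.5, with 6.5 for category 1 in seed, so category 0 lay below category 2 in place of above it.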

Other observations

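Some families outside the fixed lists were also uneven between the libraries, and were chosen here after their values were seen. The miR4393 family had 6 supported pairs in seed, 2 of them in category 0, and 0 in each other library, but 0 in seed too with Allen scores limited to 4. The miR5674 family had 9 pairs in leaf, 4 in flower, 2 in rootstem and 2 in seed, and with Allen scores limited to 4 it had 8, 4, 1 and 1. Among the m-numbered queries, m3244 had 10 pairs in seed against 1 in leaf, 1 in rootstem and 0 in flower, and m3028 had 8 in seed against 1 in rootstem and 0 in leaf and flower. With Allen scores limited to 4, m3244 had 7 in seed, 1 in leaf and 0 in the others, and m3028 had 2 in seed and 0 in the others. By contrast m4661 was spread over the plant, with 11 pairs in leaf, 10 in rootstem, 13 in flower and 9 in seed.

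Names and sequences of queries did not always match. The queries gma-miR156z-3p and gma-miR156aa-3p carry the 18 nt sequence AUUGGAGUGAAGGGAGCU, which is contained in the 21 nt sequence of gma-miR159b-3p, AUUGGAGUGAAGGGAGCUCCA. Their supported pairs numbered 5 in leaf, 4 in rootstem, 2 in flower and 4 in seed, and in each library all of these loci were also called for miR159. The miR156 counts rest on these queries alone for 2 pairs in leaf, 1 in rootstem, 0 in flower and 1 in seed. A further 10 m-numbered queries contain, or are contained in, a miR-numbered sequence. Slice positions called for both kinds of query numbered 52 in leaf, 46 in rootstem, 45 in flower and 38 in seed.

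For the patterns weighed from here on, the yield test of the seed library, its share over alignments able to pass in each library and the count of CA-repeat positions without m4142 were chosen after the data were seen.

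Of the 569 pairs supported in at least 2 single libraries, 216 were not listed at any category in the combined table. For 68.5% of them the alignment would have had a p above 0.05 in the combined table even at its strongest single-library category. The frequency f of category 2 positions in Phytozome 8 was 0.0135 in the combined table and 0.00416 to 0.00542 in the single libraries, so that category 2 was open to the first 3 alignments of a query in the former and the first 9 to 12 in the latter. A candidate explanation for these 68.5% is the p limit at this higher frequency. For the rest a fall to category 2 or 3 on pooling stays open: 100% of the unlisted pairs would have had a p above 0.05 at category 2, but an alignment that passes there passes at every category, so this value was fixed by the limit; no biological explanation was tested.

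The low number of transcription factor list pairs in seed was not set by the p limit at an unchanged category: 0% of the 93 list pairs unlisted in seed would have had a p above 0.05 there at their category elsewhere. Pairs outside the list numbered 888 in seed, 1.04 times the lowest other library, against 1013 in leaf, 856 in rootstem and 950 in flower. The miR-numbered pairs outside the list numbered 113 in seed, against 130 in leaf, 114 in rootstem and 103 in flower. These counts argue against a fall in all called pairs as large as that in the list. Most pairs outside the list were of m-numbered queries, which recurred little. Their number therefore does not measure the yield of true cuts, which stays open. A fall to category 2 that the p limit hides stays open. Among the 70 list pairs that could be listed at categories 0 to 2 in each library, seed had 55.7% (43.3 to 67.6). That interval holds the lowest other share, 65.7% in rootstem, but lies below those of leaf, 68.6%, and flower, 74.3%. Seed thus stayed lowest where the p limit could not hide such a fall, and these values neither show nor exclude this explanation. Part of the difference may be a weaker cut signal relative to other fragments of the same transcripts, which was not tested. Tissue, which the groups name, and the age of the pods and seeds remain untested.

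The seed library had 19 slice positions in target sequence with at least 4 tandem CA or AC repeats, against 1 in leaf, 0 in rootstem and 1 in flower, and 14 of the 19 were in category 0. Other simple repeats numbered 37 in leaf, 34 in rootstem, 32 in flower and 32 in seed, which in seed is 0.865 times the highest other library. CU repeats alone numbered 29, 24, 23 and 21 in the same libraries. The ratio therefore follows mainly the CU repeats. With those taken out, few positions remained in any library, and seed showed no rise near that of the CA repeats. Counts this small cannot exclude a smaller general rise of such sites in seed. Of the 19 positions, 0% would have had a p above 0.05 at their seed category in another library. For the 14 in category 0 this was fixed in advance, since seed had the strictest limit at that category. Whether a few repeat-matching queries make the excess stays open: 3 queries gave all 18 loci, gma-m4142-3p (GUGUGUGUGUGUUUGUGUCUG) alone matched 14, and without it seed had 4 positions and each other library 0. The count of positions, 19.0 times the highest other, cannot decide this, since positions cannot be fewer than their loci. Reads that match several repeat-bearing transcripts may have contributed, which the tables cannot test without read counts, and a difference between tissues is untested.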
